A study of Mus musculus with 2 samples.

How the data were processed

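The series holds 2 samples of 1 group. Both are MEL cells, a mouse erythroleukaemia line, given 2% dimethyl sulphoxide (DMSO) for 5 days, in which histone H3 trimethylated at lysine 4 (H3K4me3) was profiled by ChIP-seq. Per the labels, the samples are biological replicates 1 and 2 and the fragments fell in a size range of 150 to 350 bp. Untreated cells were not analysed here, so no change with DMSO was tested, and the only comparison between samples is the agreement of the replicates.

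The authors deposited 4 sets of called peaks on the mouse build mm10, namely 1 set per replicate, 1 set from the pooled alignments of both replicates and 1 set of replicated peaks. Per the file headers and notes deposited beside them, each replicate's set derives from that replicate's own alignments and 2 further files shared by all sets, and the replicated set derives from the pooled set and both replicates' sets. An older set on the build mm9 was deposited for the whole series, and what it was derived from is not given in the sources used here. The aligner, the peak caller, its threshold and the rule for a replicated peak are likewise not given in the sources used here. Each deposited peak has a signal value, called the enrichment value below, whose scale is not stated by the authors. The deposited p-value and q-value of each peak are given on a −log10 scale. All of these are the authors' own values per peak. The enrichment value was used to describe and rank peaks within a set and, for the agreement of the replicates, to correlate their sets. Per gene, the mean and the ratio of the replicates' values were also used, which takes both sets to be on the same scale.

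The files hold no read counts, so the sequencing depth of each replicate is unknown and no interval for a single peak was computed. Precision was taken from the 2 replicates (mean ± SD) and, for shares of peaks or genes, from 95% Wilson intervals, which cover counting error only. Genes and regions are not independent replicates, so a p-value over genes describes these 2 samples.

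Before the data were examined, the tests, the alternatives, the 27 gene lists and the rule for naming genes were fixed. Named are all measured members of the globin list and of the list for heme synthesis and iron uptake, the 10 marked genes with the highest mean enrichment value and the 10 with the widest mean domain. Of every other list, the 2 marked members with the highest mean enrichment value and the first 2 unmarked members by name are added. Some of the genes chosen this way are not reported here. Other genes that are named were chosen after their values were seen, among them the further members of short lists.

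Peaks on chromosomes 1 to 19, X and Y were used. Gene positions came from a RefSeq gene table of GRCm38, the assembly behind mm10, which gives 1 start and 1 end per gene without strand or transcripts. Strand was taken from the GENCODE M1 annotation by symbol for 18388 protein-coding genes and by synonym for 2164, which leaves 20552 of 21843 genes. The other 1291 genes, among them Hbb-bt and Hbb-bs, have no strand here and entered no test. The plan named the 5' ends of all transcripts. Since mm10 transcripts were not used here, a gene has a single 5' end, and genes whose active promoter lies inside the gene can be missed. A further comparison with the gene's 5' end alone, which the plan held, is therefore the same as what is reported. Exons, introns and untranslated regions were not annotated.

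A gene was called marked when its 5' end ± 1000 bp overlapped by at least 1 bp a peak of replicate 1 and a peak of replicate 2. Its enrichment value in a replicate is the highest among those peaks. Its domain is the widest run of peaks joined across gaps of at most 1000 bp. Each list was compared with all other protein-coding genes by Fisher's exact test. Median enrichment values and domain widths of lists with at least 5 marked members were set against 100000 random lists of the same size drawn from the marked genes, in a permutation test whose smallest p is 2e-05. All tests were two-sided, with Benjamini-Hochberg adjustment over the lists tested and a threshold of 0.05. Regions are peaks of both replicates merged where they touch. A region counts as distal when it lies more than 5000 bp from every protein-coding 5' end. Random positions came from 100 shuffles within each chromosome, between its first and last gene or peak, because chromosome lengths of mm10 were not used here.

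Alternatives were narrower and wider windows of 500 and 2000 bp, minimum −log10 q values of 2 and 5, a reciprocal overlap of 50%, the 20000 peaks with the highest −log10 p, other gaps of 0 and 3000 bp, other distances of 2500 and 10000 bp, other backgrounds and measures, and each replicate left out in turn. Chosen after seeing the data were the whole gene span ± 1000 bp, the older set on NCBIM37 transcripts and counting each pair of peaks or domains once. A background matched on CpG content and the ribosomal list without the S6 kinases and Rps19bp1 were also chosen then. The older set was annotated only with GENCODE M1 on NCBIM37, the assembly behind mm9, and no coordinate was moved between builds.

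Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap code was tested on simulated data against bedtools 2.31.1 with 1000 and 1000 intervals and found 100% of its pairs and 0 others. In simulated lists of 15 among 20552 genes, the list test passed an unadjusted 0.05 for 93.8% of lists with 90% of members marked and for 3.1% of lists marked like other genes. In simulated lists of 15 among 9960 marked genes, the width test did so for 87% of lists made 1.5-fold wider and for 7.5% of unchanged lists.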

Results

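H3K4me3, the trimethyl mark that is found at the promoters of active and poised genes, was mapped in MEL cells by sequencing of immunoprecipitated chromatin. MEL cells are transformed mouse erythroid precursors, and DMSO is a textbook inducer of their maturation towards haemoglobin-making cells. The group had 2 biological replicates, both given 2% DMSO for 5 days. Replicate 1 had 48026 peaks and replicate 2 had 46950 on chromosomes 1 to 19, X and Y, a mean of 47488 ± 761 (SD, n = 2, as for all means below). The peaks had a median width of 458 and 437 bp, covered 32.9 and 33.9 Mb, and had a median enrichment value of 5.51 and 5.31. The deposited q-value was above 0.05 for 3.85% of peaks in replicate 1 and 4.16% in replicate 2. The pooled set held 45937 peaks and the replicated set 37550. Positions are 1-based on mm10 unless another build is named, and sequencing depth is unknown because the peak sets hold no read counts.

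The first question was how far the replicates marked the same places. The strongest peaks were shared throughout and the weakest were shared less often. Of the peaks of replicate 1, 84.6% overlapped a peak of replicate 2 (95% Wilson interval 84.2% to 84.9%), and of those of replicate 2, 80.9% overlapped a peak of replicate 1 (80.5% to 81.2%). At random positions the shares were 2.30% ± 0.0652 and 2.32% ± 0.0665 (SD over 100 shuffles). With peaks split into 5 equal groups by −log10 p, all of the highest group were shared in both replicates, against 48.7% and 45.1% of the lowest group. Shared peaks of replicate 1 had a median width of 584 bp and unshared ones 188 bp. Merging gave 50676 regions, of which 34300 held both replicates, 7401 replicate 1 alone and 8975 replicate 2 alone. Across the 34300 regions, which are not independent replicates, the enrichment values had a Pearson correlation of 0.849 on the log2 scale and a Spearman correlation of 0.856. The log2 ratio of replicate 1 to replicate 2 had a median of −0.07 and an SD of 0.47, and 3.62% of regions differed by more than 2-fold. When an overlap of at least 50% of both peaks was required, the shared share was 62.4% on average.

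**Figure D1:**
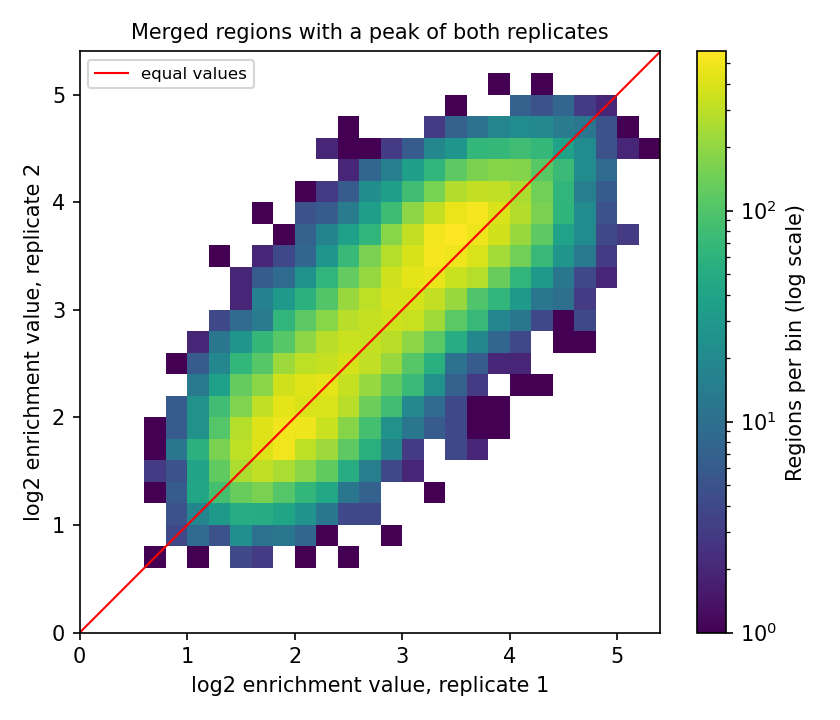
Log2 enrichment value of replicate 1 (horizontal) against replicate 2 (vertical) in the 34300 merged regions that hold a peak of both, as the number of regions per bin of 0.2 log2 units on a log colour scale. The red line marks equal values, and the Pearson correlation was 0.849.

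The mark was then placed relative to genes. Peaks were concentrated at the 5' ends of protein-coding genes, and the regions away from them were narrower and weaker. In replicate 1, 35.2% of peaks lay within 1000 bp of a 5' end (34.8% to 35.6%), and in replicate 2, 32.4% (31.9% to 32.8%), against 2.15% at random positions in each. Of the 34300 regions with both replicates, 13908 lay at such an end and 16610, or 48.4% (47.9% to 49.0%), lay more than 5000 bp away. Distal regions had a median width of 569 bp against 1225 bp at 5' ends and a median enrichment value of 4.98 against 11.4. Cliff's delta across regions was −0.674 for the enrichment value and −0.521 for width. The distal share depended on the genes counted, at 35.9% when the 5' ends of genes of every biotype were used. Distance was measured to a single 5' end per gene with a strand, so promoters inside a gene can count as distal. The strongest Gata1 peak (7964441 to 7967884 in replicate 1) is such a case, and the share can be too high for this reason.

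Of 20552 protein-coding genes, 9960 (48.5%) were marked in both replicates, 59 in replicate 1 alone and 181 in replicate 2 alone. At 3' ends, the same rule marked 1394 genes. Marked genes had a median enrichment value of 13.2 and a median domain width of 2258 bp. The highest mean values were those of Usp25, a ubiquitin protease (31.9 ± 12.1, chromosome 16, 77013684 to 77116783), and Eif4h, a translation initiation factor (30.4 ± 0.0592). Zfp758 and Zfp944 shared a single divergent promoter at 28.7 ± 8.88, and the next were Phf10, R3hdm2, Sptb, Stk38l, Dync1i2 and Cox4i1, from 28.3 to 27.5. The peak of Cox4i1 was shared with Emc8 on the other strand. The erythroid gene among these 10 was Sptb, which encodes β-spectrin of the red cell skeleton (27.7 ± 1.49, chromosome 12, 76580488 to 76710547).

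The widest domains were those of Abt1 (16535 ± 56.6 bp), Irf2bp2 (15776 ± 264 bp), Irs2 (10880 ± 258 bp) and Ppp1r9b (10765 ± 134 bp). They were followed by 3 genes of the erythroid lists, Nfe2 (10756 ± 398 bp), Car1 (10744 ± 922 bp) and Bcl11a (10676 ± 61.5 bp). Zfp36l2 and Tmem131 came next. Rhof, the last of the 10, shared a domain of 9887 ± 82.0 bp with Setd1b, an H3K4 methyltransferase on the other strand. Across marked genes, the widths of the replicates had a Pearson correlation of 0.918 on the log2 scale and the enrichment values one of 0.634.

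The next comparison asked whether genes of red cell development carried the mark more often than other genes. Of the 5 erythroid lists, 4 did. Genes for heme synthesis and iron uptake were marked in 15 of 16 cases, against 48.4% of all other genes (odds ratio 16.0, 95% interval 2.11 to 121, adjusted p = 0.000515 by Fisher's exact test over 27 lists). Cpox, which makes protoporphyrinogen, had the highest value of the list at 24.3 ± 0.845. Alas2, the erythroid form of the first enzyme of the pathway, stood at 18.0 ± 4.19 (chromosome X, 150547417 to 150570622). Further pathway enzymes were Ppox (16.4 in replicate 1 and 13.6 in replicate 2), Urod at 14.8 ± 0.724, Uros at 13.3 ± 1.04, Alad at 11.3 ± 2.59 and Fech at 10.8 ± 1.39. Urod shares its strongest peaks with Hectd3 and Uros with Bccip, each on the opposite strand. Of the transporters and receptors, Abcb10 had 16.7 ± 4.56, Tfrc, the transferrin receptor, 15.9 ± 3.96, Flvcr1 12.3 ± 1.16, Slc25a38 11.8 ± 2.72, Slc11a2 10.4 ± 0.775 and Tfr2 9.20 ± 3.17. Steap3 had the lowest value, 3.83 ± 0.350. Slc25a37, the mitochondrial iron importer mitoferrin, had no peak of either replicate anywhere from 69241848 to 69285544 on chromosome 14 or within 1000 bp of that span, whereas the older set has a peak at its 5' end (mm9, chromosome 14, 69900853 to 69903783).

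Erythroid transcription factors were marked in 13 of 15 cases (odds ratio 6.92, 1.56 to 30.7, adjusted p = 0.00525 by Fisher's exact test). The highest values were those of E2f2 (22.9 ± 4.44) and Klf1, the activator of adult globin transcription (20.7 in replicate 1 and 21.3 in replicate 2, chromosome 8, 84901982 to 84905291). Gata1 and Ldb1 were unmarked at the gene's 5' end but held strong peaks inside the gene. In Gata1 (chromosome X, 7959260 to 7976663, read from the higher coordinate), the strongest peak ran from 7964441 to 7967884 with a value of 21.1 in replicate 1 and from 7964434 to 7967875 with 15.02 in replicate 2. In Ldb1 the strongest peaks had values of 17.1 and 18.2.

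Genes of the red cell membrane and the carbonic anhydrases were marked in 19 of 21 cases (odds ratio 10.1, 2.36 to 43.5, adjusted p = 0.000289 by Fisher's exact test). Sptb and the glycophorin gene Gypc led with 27.7 ± 1.49 and 24.6 ± 2.47. Slc4a1, the anion exchanger band 3, and Epb42, protein 4.2, were marked at low values of 4.24 ± 0.384 and 3.97 ± 0.209. Add2 and Ank1 were unmarked at the 5' end, and Ank1 had peaks of 24.1 and 16.0 inside the gene. Late maturation genes were marked in 13 of 15 cases (odds ratio 6.92, 1.56 to 30.7, adjusted p = 0.00525 by Fisher's exact test), led by the cell cycle inhibitor Cdkn1b (21.6 ± 8.82) and by Trim10 (18.7 ± 1.24). Alox15 and Xpo7 were the unmarked ones, both with peaks inside the gene or within 1000 bp of it. Against genes drawn from the same deciles of promoter CpG content, the late maturation list no longer passed (adjusted p = 0.0574, permutation of 10000 draws). Over all settings, the odds ratio ranged from 7.75 to 33.5 for the heme and iron list, 5.98 to 31.5 for the transcription factors and 6.09 to 29.2 for the membrane list, and that of late maturation was at least 3.93. Together the 5 lists had 64 of 75 genes marked, or 85.3% (75.6% to 91.6%).

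Globins did not stand apart, with 4 of 8 measured genes marked (odds ratio 1.06, 0.266 to 4.25, adjusted p = 1 by Fisher's exact test). The odds ratio depended on the setting without a call, from 0.161 within 500 bp (adjusted p = 0.091 by Fisher's exact test) to 4.32 against genes of the same CpG deciles (adjusted p = 0.0825, permutation test). The marked genes were all in the α-globin locus on chromosome 11. Hbq1b, a θ-globin gene, had the strongest peak, with a mean value of 15.7 ± 2.09. The peak ran from 32287373 to 32289587 in replicate 1 and to 32289466 in replicate 2. It thus began inside the gene and ran past the 3' end at 32287912. The peaks nearest the 5' end of Hbq1b (32286964) had 4.08 in replicate 1 and 4.01 in replicate 2. The adult genes Hba-a1 and Hba-a2 had values of 4.93 ± 0.964 and 2.88 ± 0.181, and Hbq1a had 3.29 in replicate 1 and 2.71 in replicate 2. Hba-a2 counted as marked through peaks past its 3' end at 32297310, which began at 32297427 in replicate 1 and 32297464 in replicate 2. The peaks of Hbq1a ran over its 3' end at 32300873. These genes are short, so their marks fell within 1000 bp of the 5' end without lying at it. No peak of either replicate covered the 5' end itself of Hba-a1 (32283672) or Hba-a2 (32296492), and the strongest peak of Hba-a1 lay at its 3' end, from 32284407 to 32285012 in replicate 1. Weaker peaks lay upstream of Hba-a1, such as 32282657 to 32282946 (3.62) in replicate 1 and 32283190 to 32283411 (2.90) in replicate 2. The adult copies are nearly identical, so their values are uncertain. The embryonic genes Hba-x, Hbb-y, Hbb-bh1 and Hbb-bh2 were unmarked. The adult β-globin genes had no strand here and were read by position alone. Hbb-bt (chromosome 7, 103812524 to 103813923) had its strongest peaks at 103812016 to 103812768, with 13.5 in replicate 1, and at 103812025 to 103812754, with 9.30 in replicate 2. Hbb-bs (103826523 to 103827928) had 4.30 and 2.57. These peaks lay over the lower-coordinate end of each gene. Hbb-bh2, Hbb-bh1 and Hbb-y beside them are read from the higher coordinate, so these may be 3' ends rather than promoters. Near the higher-coordinate end of Hbb-bt, the peaks had 4.99 in replicate 1 and 5.11 in replicate 2.

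**Figure D2:**
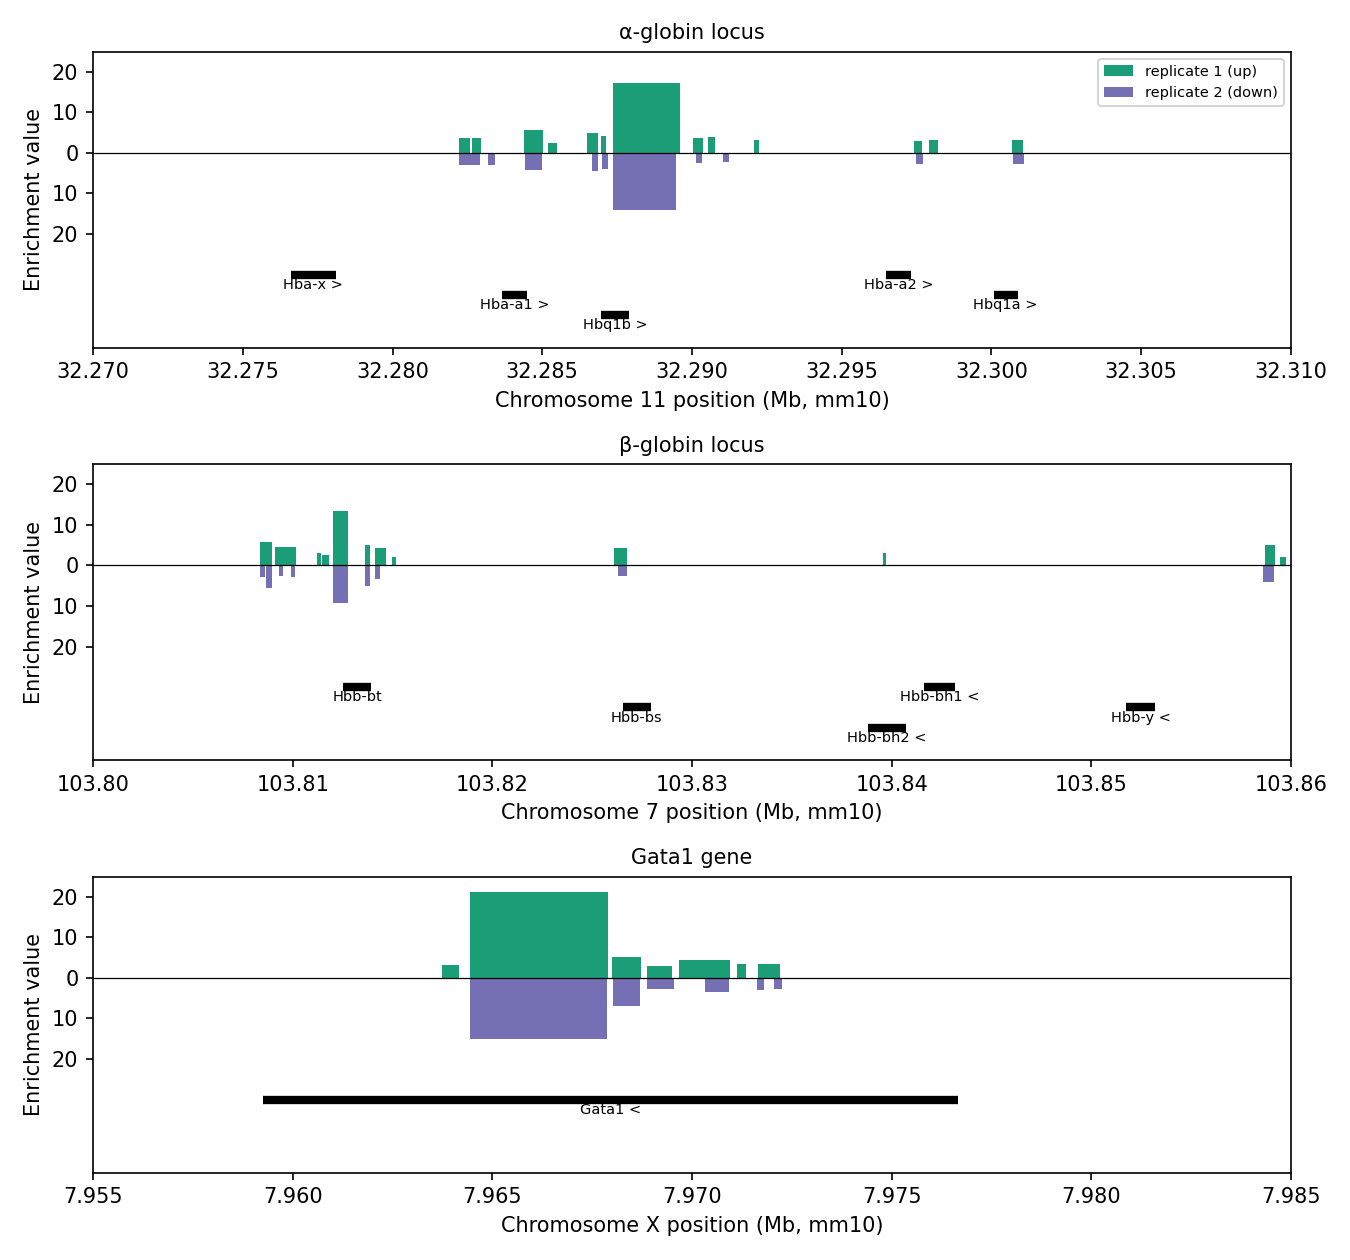
Peaks of replicate 1 (green, upwards) and replicate 2 (violet, downwards) at the α-globin locus, the β-globin locus and Gata1, with position in Mb on mm10 on the horizontal axis, the enrichment value as bar height and genes as black bars whose arrowheads give the strand where one was used. The strongest α-globin peak (17.1 and 14.2) begins inside Hbq1b and runs past its 3' end, and the strongest Gata1 peak (21.1 in replicate 1) lies inside the gene.

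Lists of the other blood lineages were compared in the same way, as these are fates that a red cell precursor has left. Granulocyte and macrophage genes were marked in 2 of 19 cases (odds ratio 0.125, 0.0289 to 0.541, adjusted p = 0.00166 by Fisher's exact test), namely Cebpa (9.19 ± 3.78) and Lyz2 (2.61 and 3.39 in the replicates). Adgre1 and Cd14 were among the unmarked. B cell genes were marked in 1 of 12 cases, Vpreb1 (8.02 and 12.3 in the replicates), with Blk among the unmarked (adjusted p = 0.00939 by Fisher's exact test). T and NK cell genes were marked in 2 of 16 cases, Gata3 (10.3 ± 0.483) and Tcf7 (7.66 ± 3.86), with Bcl11b and Cd3d unmarked (adjusted p = 0.00665 by Fisher's exact test). The B cell and T and NK cell calls ended without replicate 1 (adjusted p = 0.0523 and 0.0991 by Fisher's exact test) and over the gene span (0.275 and 0.112), and the granulocyte and macrophage odds ratio was 0.273 without replicate 1 (adjusted p = 0.0307). All 3 ended against genes of the same CpG deciles (adjusted p = 0.0955 for granulocyte and macrophage, 0.3 for B cell and 0.243 for T and NK cell genes, permutation test).

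Stem and progenitor, megakaryocyte and mast cell genes did not pass the test. Stem and progenitor genes were marked in 6 of 17 cases (odds ratio 0.580, 0.214 to 1.57, adjusted p = 0.363 by Fisher's exact test), with Myb (19.5 and 18.6 in the replicates) and Mllt3 (14.6 ± 0.228) highest and Cd34 and Erg unmarked. Kit, the stem cell factor receptor, was unmarked at its 5' end, and its strongest peaks inside the gene had values of 6.79 and 10.6. Megakaryocyte and platelet genes were marked in 7 of 16 cases (adjusted p = 0.836 by Fisher's exact test), led by Pf4, platelet factor 4 (16.7 ± 1.13), and Runx1 (13.3 ± 3.16), with Fli1 and Gp1bb unmarked. The direction of both lists depended on the setting, without a call. The odds ratio of stem and progenitor genes was 2.20 over the gene span and 0.343 against genes of the same CpG deciles, and that of megakaryocyte and platelet genes was 0.827, 0.337 in the older set and 2.41 against the same CpG deciles. Mast cell and basophil genes were marked in 2 of 10 cases, Mitf (12.4 ± 1.28) and Gata2 (11.8 ± 2.72), with Cma1 and Cpa3 unmarked (odds ratio 0.266, adjusted p = 0.136 by Fisher's exact test, and 0.822 against the same CpG deciles).

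Genes of cell growth were nearly all marked. Cell cycle genes were marked in 21 of 21 cases (adjusted p = 1.32e-06 by Fisher's exact test), with Mki67 at 27.1 ± 1.78 and Pcna, which shares its promoter with Cds2, at 26.5 and 27.5 in the replicates. Genes named Rpl or Rps were marked in 84 of 95 cases (odds ratio 8.18, 4.36 to 15.3, adjusted p = 2.06e-15 by Fisher's exact test). This list was drawn by name, and 11 of its genes are the S6 kinases and Rps19bp1, which are not ribosomal proteins. Without these, 75 of the 84 genes left were marked (odds ratio 8.92, 4.47 to 17.8, adjusted p = 3.89e-14 by Fisher's exact test). The genes left still include some whose names are those of pseudogenes or related genes, such as Rpl31-ps12, Rpl34-ps1 and Rps23rg1, all unmarked. Rps2 was unmarked as well, with a peak in 1 replicate. Rpl24 (24.1 ± 12.8) and Rpl11 (18.8 ± 3.98) were highest, and the unmarked included the retrogene Rpl10l and Rpl31-ps12. Replication-dependent histone genes were marked in 56 of 61 cases (91.8%, adjusted p = 4.13e-12 by Fisher's exact test). The divergent pair H2bc9 and H3c7 led with 14.1 ± 1.28, while H2ac1 and H2ac24 were unmarked. Writers and erasers of H3K4 methylation themselves were marked in 15 of 16 cases (odds ratio 16.0, adjusted p = 0.000515 by Fisher's exact test). The demethylases Kdm5b (23.8 ± 0.212), whose peak also reaches Mgat4e, and Kdm5c (20.3 ± 3.73) were highest, and Dpy30 was the unmarked member. The size of these differences depended on the background. Against genes of the same CpG deciles, the odds ratios fell to 16.2 for cell cycle, 3.27 for the Rpl and Rps list, 3.01 for histone and 6.45 for H3K4 writer and eraser genes (adjusted p = 0.00589, 0.000675, 0.0234 and 0.0486, permutation test).

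Housekeeping genes were marked in 12 of 13 cases, led by Pgk1 (21.9 and 20.2 in the replicates) and Gapdh (19.9 ± 4.32), with Ywhaz unmarked (adjusted p = 0.00267 by Fisher's exact test, and 0.0961 against genes of the same CpG deciles, permutation test). Interferon response genes were marked in 10 of 12 cases, with Irf7 (17.7 ± 1.14) and Isg15 (14.6 ± 0.0102) highest and Ifit3 and Oas1a unmarked (odds ratio 5.32, 1.17 to 24.3, adjusted p = 0.0258 by Fisher's exact test). This call ended when olfactory and vomeronasal receptor genes were left out of the background (adjusted p = 0.0563 by Fisher's exact test), over the gene span (0.172) and in the older set (odds ratio 3.04, adjusted p = 0.106), and it was stronger against genes of the same CpG deciles (0.000675, permutation test). Apoptosis and p53 target genes were marked in 10 of 14 cases, which did not pass (adjusted p = 0.136 by Fisher's exact test), although it did without replicate 1 (adjusted p = 0.0468), with a peak of either replicate (0.0481), within 2000 bp (0.0174), over the gene span (0.0176) and in the older set (odds ratio 13.2, adjusted p = 0.00175). Against genes of the same CpG deciles the list was far from passing (adjusted p = 0.913, permutation test). Mdm2 (19.1 ± 2.27) was highest, and Bcl2l1 and Cdkn1a were unmarked at the 5' end.

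Genes of unrelated tissues mostly lacked the mark. None of 12 hepatocyte genes (such as Alb and Afp), 12 skeletal muscle genes (such as Acta1 and Ckm) and 10 pluripotency genes (such as Dppa3 and Dppa5a) was marked, with adjusted p = 0.00116, 0.00116 and 0.00366 by Fisher's exact test. Against genes of the same CpG deciles the hepatocyte call ended (adjusted p = 0.0788, permutation test) and the muscle call passed narrowly (0.0486). Developmental transcription factors were marked in 1 of 19 cases, Neurog2 (8.46 ± 2.75), with Dlx5 and Foxa2 unmarked (adjusted p = 0.000289 by Fisher's exact test). Hox genes were marked in 5 of 39 cases (odds ratio 0.156, 0.0610 to 0.399, adjusted p = 1.51e-05 by Fisher's exact test). These were Hoxc9 (14.3 ± 2.48), Hoxc10 (13.8 ± 2.68), Hoxb13, Hoxc6 and Hoxd8, with Hoxa10 among the unmarked. Neuronal genes and stromal and endothelial genes were each marked in 4 of 14 cases and did not pass (adjusted p = 0.205 by Fisher's exact test). Neuronal genes did pass as less often marked when a −log10 q of at least 5 was required (odds ratio 0.0850, adjusted p = 0.00367 by Fisher's exact test) and in the older set (0.0778, adjusted p = 0.00329). The odds ratio of stromal and endothelial genes turned from 0.425 to 1.10 against the same CpG deciles and 1.22 over the gene span, without a call. Syp (9.10 ± 1.38), Slc17a7 (5.77 ± 3.16), Vim (14.5 ± 6.50) and Pdgfrb (10.9 and 13.1) were highest, and Dcx, Gad1, Acta2 and Cdh5 were unmarked.

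Of 1103 olfactory receptor genes, 3 were marked, Olfr1509 (7.50 ± 2.75), Olfr59 (6.91 ± 1.92) and Olfr872, while Olfr1 and Olfr10 were among the unmarked (odds ratio 0.00260, adjusted p = 3.87e-321 by Fisher's exact test). Of 349 vomeronasal receptor genes, 2 were marked, Vmn1r4 and Vmn2r29 (odds ratio 0.00593, adjusted p = 1.61e-96 by Fisher's exact test), while Vmn1r1 and Vmn1r10 were not. Both odds ratios depended mostly on the background. Against genes of the same CpG deciles, of which 10.2% and 7.51% would be marked, they were 0.0241 for olfactory and 0.0710 for vomeronasal receptors (adjusted p = 0.000675 for each, permutation test). Without replicate 2, the olfactory odds ratio was 0.00515 against all other genes. The value of Vmn1r4 (18.0 ± 4.66) came from a peak shared with Nt5c3, whose 5' end lies 94 bp away on the other strand.

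**Figure D3:**
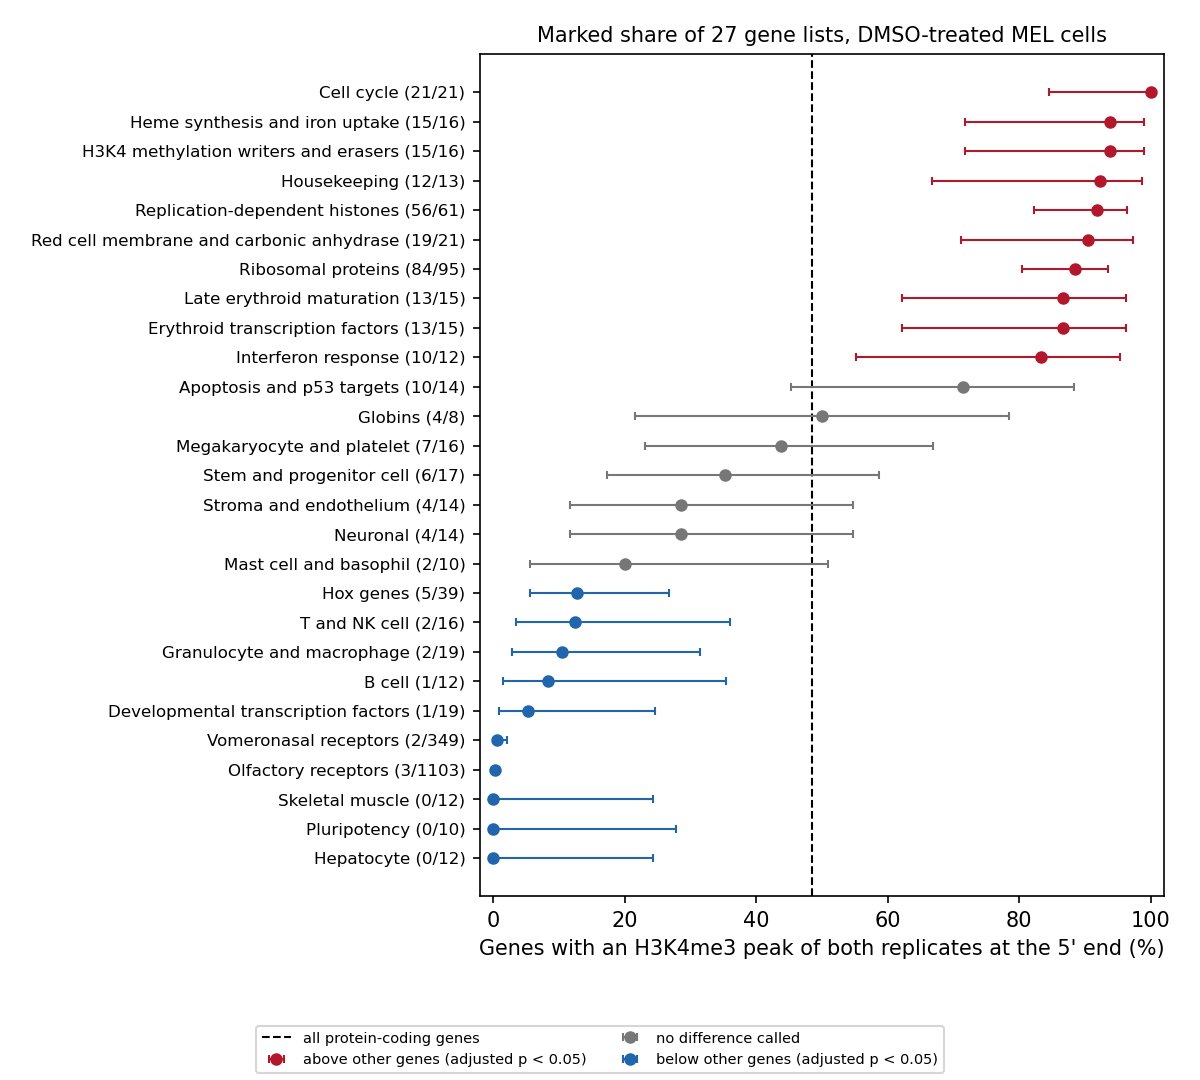
Percentage of measured members marked in both replicates (horizontal axis) for each of 27 gene lists, with 95% Wilson intervals as bars, the number marked over the number measured beside each name and the share of all protein-coding genes (48.5%) as a dashed line. Colours give the adjusted Fisher's exact test, with 10 lists above other genes, 10 below and 7 not called, and the ribosomal list as drawn includes the 11 other genes.

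Among marked genes, the height of the mark differed between few lists. Erythroid transcription factors had a median enrichment value of 16.6 against 13.2 for all marked genes (13 genes, adjusted p = 0.0465, permutation test over 14 lists). That call ended without replicate 1 (adjusted p = 0.56) and without replicate 2 (0.468, permutation test). Megakaryocyte and platelet genes (5.22, 7 genes, adjusted p = 0.00028, permutation test) and replication-dependent histone genes (8.45, 56 genes, adjusted p = 0.00028, permutation test) had lower medians. The other 11 lists did not pass, although cell cycle genes (15.7, adjusted p = 0.0531) did with each pair of peaks counted once (0.0455, permutation test). Interferon response genes (10.9, adjusted p = 0.183) were lower under at least 1 alternative, where the adjusted p fell to 0.0199 (permutation test). Medians were 12.3 for heme synthesis and iron uptake, 13.3 for the red cell membrane and 15.1 for late maturation.

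Domain width set the erythroid lists apart more widely than height. Among marked genes, erythroid transcription factors had a median domain width of 5412 bp, the red cell membrane list 4698 bp and the heme and iron list 3903 bp, against 2258 bp for all marked genes (adjusted p = 9.33e-05, 9.33e-05 and 0.0007, permutation test over 14 lists). Without joining across gaps, the membrane list was 1.30 times as wide as marked genes (adjusted p = 0.0454) and the heme and iron list 1.38 times (0.0368, permutation test), against 2.08 and 1.73 times with joining. Nfe2, Bcl11a, Foxo3 (8900 ± 469 bp) and Tal1 (8306 ± 63.6 bp) were the widest of the factors, and Car1 and Car2 (7526 ± 1114 bp) the widest of the membrane list. In the heme and iron list, Alad (6093 ± 349 bp) and Abcb10 (5564 ± 168 bp) had the widest domains. Late maturation genes had a median of 2676 bp and did not pass (adjusted p = 0.254, permutation test).

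Wider domains were also found outside the erythroid lists. Histone genes had a median of 4066 bp (adjusted p = 9.33e-05, permutation test), but their peaks lie in dense clusters, and without joining across gaps their median was 0.861 times that of marked genes. Apoptosis and p53 targets (3596 bp, adjusted p = 0.0114), ribosomal protein genes without the 11 others (2788 bp, adjusted p = 0.00129) and stem and progenitor genes (3957 bp, adjusted p = 0.0131) were also wider by the permutation test, the last with 6 marked genes and not without replicate 1 (adjusted p = 0.0769, permutation test). The apoptosis call ended when gaps of up to 3000 bp were joined (adjusted p = 0.0893, permutation test). Hox genes (3437 bp, 5 marked genes) did not pass (adjusted p = 0.0864, permutation test), but did at gaps of 3000 bp (2.63 times the median of marked genes, adjusted p = 0.00916), at gaps of 0 bp (0.0211) and without replicate 1 (0.0483). H3K4 writers and erasers (2937 bp, adjusted p = 0.0766) and housekeeping genes (3088 bp, adjusted p = 0.053) did not pass either, but did at gaps of 3000 bp (adjusted p = 0.00392 and 0.0274, permutation test), housekeeping genes also with each pair of domains counted once (0.038). Interferon response genes were narrower, at 1442 bp (adjusted p = 0.0126, permutation test), which ended without joining across gaps (adjusted p = 0.17).

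**Figure D4:**
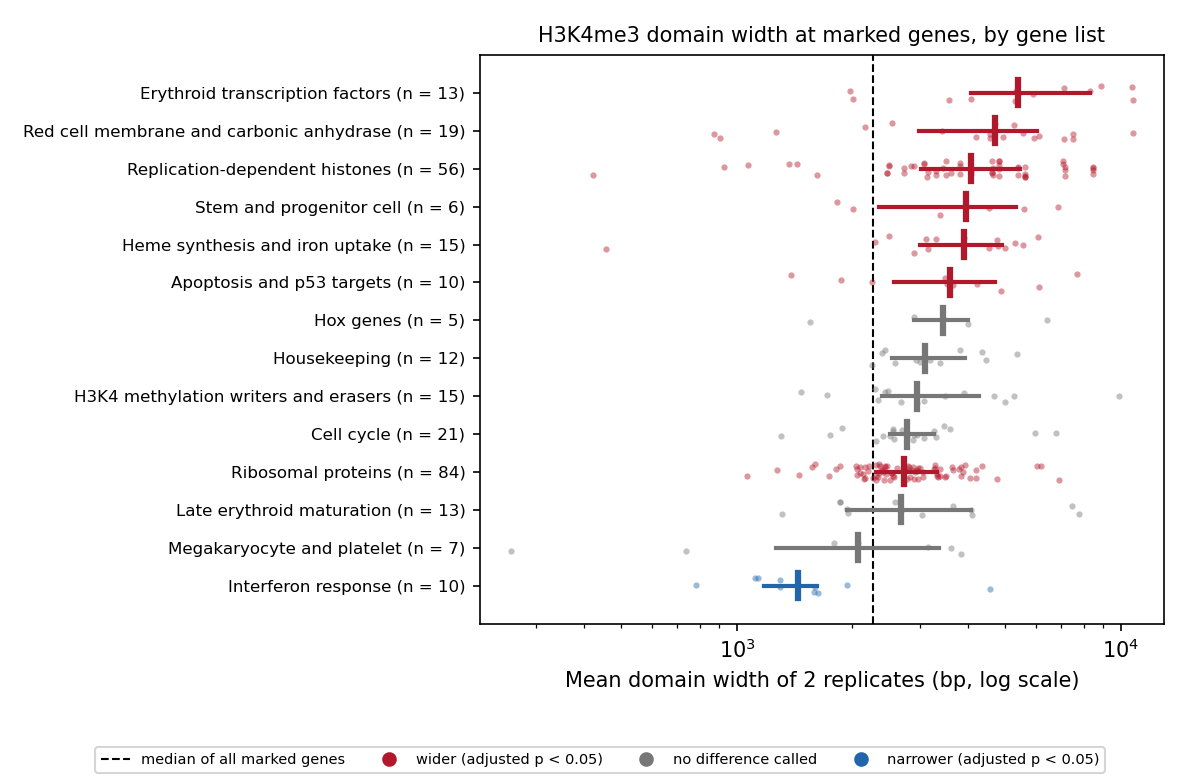
Mean H3K4me3 domain width of the 2 replicates in bp on a log axis, with a dot for each marked gene, a thick bar for the quartiles and a vertical tick for the median of each list with at least 5 marked genes. The dashed line is the median of all marked genes (2258 bp), and erythroid transcription factors have the widest median (5412 bp).

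The older set on mm9 held 15810 peaks with a median width of 1699 bp, fewer and wider than the mm10 sets. Of these, 62.2% (61.4% to 62.9%) lay within 1000 bp of the 5' end of a protein-coding transcript of NCBIM37, and 57.3% within 1000 bp of the 5' end of a gene. It marked 10085 of 20303 genes matched by name, including 9399 of the genes marked by both replicates on mm10 (94.9%). A further 686 genes were marked by the older set alone and 504 by the mm10 replicates alone. The older set was read at the 5' ends of all protein-coding transcripts and the replicates at a single 5' end per gene. These counts therefore mix the unlike rules with differences between the peak sets. Of the genes marked by the older set alone, 41 had no peak of both replicates in or near the gene. With all transcripts counted, the older set marked Gata1, Ldb1, Add2, Ank1, Xpo7 and Slc25a37, so that 70 of the 75 erythroid genes had a peak at a 5' end in either set. Chromosome 11 held 7.93% of the peaks of replicate 1 and 8.31% of the older set, chromosome 9 held 5.30% and 6.24%, and chromosome 14 held 3.43% and 4.16%.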

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

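Replicate 1 had 12 peaks and replicate 2 had 10 peaks on scaffolds outside chromosomes 1 to 19, X and Y, which no comparison used. No explanation was tested.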

How the results depend on the processing

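The settings with the older set, the gene span, distinct pairs, CpG deciles and the shorter ribosomal list were chosen after seeing the data. Joining peaks across 1000 bp gave 27466.5 peaks per replicate with a median width of 1010 bp, and minimum −log10 q values of 2 and 5 gave widths of 530 and 761 bp. The shared share was 62.4% with reciprocal overlap, 89.2% at a −log10 q of 5 and 91.4% over the 20000 top peaks. The correlation was 0.901 for −log10 p, 0.784 at a −log10 q of 5 and 0.823 over the replicated set. The share of peaks at 5' ends was 30.2% within 500 bp, 39.2% within 2000 bp, 46.6% at a −log10 q of 5, 40.6% for all biotypes and 62.2% in the older set. The distal share was 54.3% beyond 2500 bp, 41.0% beyond 10000 bp, 39.4% at a −log10 q of 5 and 35.9% for all biotypes. The number of marked genes stayed within 1.5 times under every setting run.

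Lists called above numbered 8 to 11 in all settings. Lists below numbered 8 to 11, except 6 against the same CpG deciles, where the odds ratio of the late maturation list fell to 3.93 without a call. The odds ratios of the heme, transcription factor and membrane lists kept their calls throughout. For height, the number of lists above was 0 with −log10 p, 0 without either replicate, 2 with distinct peak pairs and 7 with width times height. The number of lists below in height was 2 to 3. The transcription factors' ratio to all marked genes was 1.21 with −log10 p and 1.07 to 1.14 without a replicate, with no call. With width times height, the ratio was 1.79 for the membrane list, and it turned above 1 for the heme (1.45), stem cell (1.87) and apoptosis lists (1.78), since this measure contains width. For width, 0 lists were below at a gap of 0 bp, where the histone ratio reversed to 0.861, and 1 to 2 without a replicate. Other causes were not tested. With 2 replicates, leaving out 1 moves a mean by less than its SD by construction, so such values of single genes say nothing about stability. No paired analysis was possible because the series has 1 group. Unknown depth limits how far weak peaks can be read.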

Other observations

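Of the tests in this part, the comparison with genes near added sequence was chosen only after its result could be seen, and the choice of patterns followed from the data. Marked genes were common where the 5' end was rich in CpG. CpG content was read at the gene's GENCODE M1 5' end on NCBIM37 and the mark at the RefSeq 5' end on mm10. These positions can differ, so a low CpG ratio need not be that of the marked promoter. Of genes in the highest decile of the CpG ratio (observed over expected, 5' end ± 500 bp on NCBIM37), 81.1% were marked, against 5.16% in the lowest decile, and the median domain width of marked genes was 2813 and 1546 bp. In the 2 lowest deciles, 325 of 4112 genes (7.90%) were marked. The widest domains among these were those of Car1 (10744 ± 922 bp), Lpxn (9152 ± 293 bp, shared with Zfp91), Vmn1r4 (shared with Nt5c3), Btk (6920 ± 701 bp, shared with Rpl36a) and Kel, the Kell blood group gene (5954 ± 519 bp). Of the 15 erythroid list members in these deciles, 10 were marked (p = 1.75e-08 by Fisher's exact test against the other genes of the deciles). The globin list, with a median CpG ratio of 0.152, lies largely in these deciles, whose upper bound is 0.191. Some globins counted as marked through peaks at or past the 3' end, so this count is not one of marked promoters alone.

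A hypothesis of this re-analysis was that CpG content explains why erythroid lists are marked so often. The 75 erythroid genes were marked in 85.3% of cases, against 46.3% expected from genes of the same CpG deciles, a difference of 39.0 percentage points (p = 0.0002, the smallest that 10000 draws can give in this permutation test). The values argue against CpG content, as measured on NCBIM37, as the whole cause. Genes with a CpG-poor 5' end on NCBIM37 were rarely marked in these cells, and whether the marked ones are in tissue-specific use was not tested. Among the widest of them, Car1 and Kel were in the erythroid lists, others such as Pign and Purb were not, and several shared a domain with a neighbour.

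Replication-dependent histone genes stood differently in the replicates. Their median percentile of enrichment among the 9960 marked genes was 27.3 in replicate 1 and 5.69 in replicate 2, with 54 of 56 genes ranked higher in replicate 1. Their median log2 ratio of replicate 1 to replicate 2 exceeded that of all marked genes by 0.53 (p = 2e-05, the smallest that the permutation test can give, adjusted p = 0.00028 over 14 lists). Against GC content, the excess was 0.40 after the median of each GC decile was subtracted, against the level of enrichment it was 0.63 after decile medians of enrichment were subtracted, and over 43 distinct peak pairs it was 0.55. A difference in how many cells were in S phase, or reads shared between near-identical histone genes, may lie behind the rest, and neither these nor any biological explanation was tested.

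The adult α-globin genes, whose transcripts are abundant in red cell precursors, had no peak over their 5' ends. Among marked genes, 42.4% had a peak of both replicates over the 5' end itself. The share of marked genes with no peak of either replicate there was not computed, so how common this is remains unknown. The strongest peak beside Hba-a1 had a −log10 p of 30.8 in replicate 1 and 21.3 in replicate 2, above the medians of all peaks (14.2 and 13.3), and that beside Hba-a2 had 9.57 and 8.18. Reads shared between the copies are a candidate explanation. On NCBIM37, 9.69% of the 36-base words that start within 500 bp of both 5' ends occur once on chromosome 11, against 100% at Hba-x and 89.0% at Slc4a1. The adult β-globin genes of NCBIM37, Hbb-b1 and Hbb-b2, had 80.8% and 71.7% on chromosome 7. On mm10, no peak covered the higher-coordinate end of Hbb-bt or Hbb-bs, but their 5' ends were not assigned here. Few unique words are what shared reads need as an explanation, but they do not show that the mark was lowered by it. Slc4a1 had a low value despite its mostly unique words. Hbq1a and Hbq1b differed in enrichment at 60.2% and 60.6%. That pair cannot decide, since the peaks of Hbq1a and most of the peak of Hbq1b lay outside the windows of words. The explanation therefore stays open. Hba-x cannot decide it, since Hba-x is an embryonic gene and the embryonic globin genes were all unmarked. The read length and the treatment of reads with several matches are not given in the sources used here, and no biological explanation was tested.

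There were 41 genes with an older-set peak at a 5' end and no peak of both replicates on mm10 in or near the gene, among them Slc25a37 and its neighbour Entpd4. Sequence added or duplicated in GRCm38 is a candidate explanation for part of them. Of the 41 genes, 56.1% lay within 500000 bp of a protein-coding gene without a counterpart by name on NCBIM37, against 39.1% of the 9399 genes marked in both sets (odds ratio 1.99, 1.07 to 3.69, p = 0.0359 by Fisher's exact test). A gene can lack a match by name without its sequence being new, so this share cannot decide. Weak older peaks cannot be told apart from added sequence. The median −log10 p was 18.8 in the 41 genes and 59.0 in genes marked in both sets, between the bounds set for and against. No biological explanation was tested.

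List members without a mark at the gene's 5' end were counted separately. In the 10 lists marked above other genes there were 27 such members (2 of them S6 kinase genes of the list drawn by name), of which 11 had peaks of both replicates inside or near the gene and 10 had an older-set peak at the 5' end of some transcript. The older-set share is 37.0%, against 6.60% of all unmarked genes (p = 4.4e-06 by Fisher's exact test). The 10 lists were picked by the same mm10 marks, and the unmarked genes include nearly all olfactory and vomeronasal receptors. The contrast may therefore follow in part from these choices. The share with peaks inside or near the gene was not set against other unmarked genes. A peak of a single replicate at the 5' end was found for 1 of them, Rps2.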
